A study of Mus musculus with 5 samples.

How the data were processed

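The series holds 5 single-cell RNA-seq libraries of fluorescent cells sorted from mouse arteries. Cre driven by the lysozyme M locus had switched on the reporter tdTomato in these cells. The libraries were made with a droplet kit that counts transcripts near their 3' ends with unique molecular identifiers (UMIs). Groups were taken from the library titles: WT after 12 weeks of diet (replicates 1 and 2), WT after 30 weeks (replicates 1 and 2), and KO after 12 weeks (1 library).

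Per the file headers and the labels, the deposited values are UMI counts per gene and barcode, whole numbers with no normalization, over 31053 genes. Per the submitters' processing notes, the authors used Cell Ranger 5.0.0 and the genome build mm10. Per the file headers, 4 files came from version 5.0.0 and hold called cells alone, while the file of WT 30-week replicate 2 names Cell Ranger 4 and holds every barcode, empty droplets included. Gene symbols and identifiers came from the files. Coordinates came from a GENCODE annotation of GRCm38, which is the sequence of mm10, and are 1-based.

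The files held 98748261 and 109599241 UMIs for WT 12-week replicates 1 and 2, 159976196 and 129742619 for WT 30-week replicates 1 and 2, and 105481312 for the library labelled KO. A barcode was kept with at least 1000 UMIs, at least 500 genes and at most 10.0% mitochondrial UMIs. In the file with all barcodes a cell call came first: at least 2502 UMIs, which is the 99th percentile of its 10000 largest barcodes divided by 10. In the called-cell file of WT 30-week replicate 1 the lowest barcode had 2218 UMIs, against 500 in the other called-cell files. Doublets were scored against simulated doublets (2 per cell) among each cell's neighbours, and the highest scores were removed at a rate of 0.008 per 1000 cells. This removed 6441 of 59309 barcodes and left 52868 cells.

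Cells were scaled to 10000 UMIs and log-transformed, and 2000 variable genes, 30 principal components, 15 neighbours and Leiden resolution 1.0 gave 27 clusters (scanpy 1.11.5, igraph 0.11.9, scikit-learn 1.9.0, numpy 2.4.6, scipy 1.17.1, pandas 2.3.3, Python 3.11.15). No cell annotation was used. Clusters were named from markers fixed before the data were examined, with at least 3 markers detected, from fold changes over the other clusters with 10 CPM added. A cluster kept its name only if its 10 leading genes did not hold more markers of another class. A cluster of low UMI count also had to hold markers at a median of at least 1/3 of the highest cluster's level. That naming rule was revised after the data were seen. It went through 3 versions, all before the tests of the final version were run. Class names in the text stand for "macrophage-like" and so on. A cluster led by Chil3 and Arg1, a cluster led by Lyz1 and Ctsk, and a set of mixed clusters of low UMI count stayed unnamed. A difference from the study in class sizes may come from these rebuilt names.

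UMI counts were summed per library and class, because cells are not replicates. The sums were tested with edgeR 4.0.16 (TMM factors, filterByExpr, glmQLFit with robust estimation, glmQLFTest; R 4.3.3) in a model with 3 groups over all 5 libraries, which leaves 2 residual degrees of freedom. Adjusted p-values are Benjamini-Hochberg values with a threshold of 0.05. The library labelled KO has no replicate and is assumed to vary like the other groups. The labels call the WT libraries biological replicates without naming animals, so p-values measure the spread between these libraries. Macrophages were tested over 13987 genes, and classes or macrophage subtypes were tested where every library had at least 50 cells. The test of Srsf3 against endothelial cells is an exception, since it includes neutrophils, with 41 and 5 cells in the WT 30-week libraries. Numbers of cells per class were tested with edgeR's quasi-likelihood test, with the number of kept cells as offset. Gene lists (42 fixed before the data were examined, 40 with enough measured genes to test) were tested with camera from limma 3.58.1 at a preset inter-gene correlation of 0.01, and again with an estimated correlation. The lists of mast cell and adipocyte markers were not tested. CPM values of macrophage genes are TMM-scaled unless called unscaled. The effect on Srsf3 in 7 classes was set against that in endothelial cells in an interaction model over library and class, chosen after the data were seen. Shares of single libraries have exact (Clopper-Pearson) binomial intervals at a level of 0.95, which cover counting error only.

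The genes named in macrophages follow a rule fixed before the data were examined: the 10 called genes of largest log2 fold change in each direction with a mean of at least 20 CPM in the higher group and no overlap between libraries, leaving out predicted, sex-linked and other-cell-type genes; where under 5 passed, the 10 of smallest p, as values that did not pass; the 3 members of smallest p in each list with at least 10 CPM (at most 2 in a list with no call); and Srsf3. In other classes the 5 called genes of smallest p with at least 20 CPM are named. The log2 fold change of a gene with almost no UMIs in a group depends on the prior count, so such genes are given as CPM.

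The gene and list tests were tested on simulated data drawn from the real libraries' means and sizes (10 draws of 13987 genes, 200 changed). In the time comparison 23.3% of genes changed 2-fold and 94.1% of genes changed 4-fold were called, 11.1% of calls fell on unchanged genes, and draws with nothing changed gave 0 to 4 calls. In the KO comparison the values were 7.8%, 75.0%, 8.91% and 0 to 4. At most 1 of the 40 lists was called with nothing changed. Genes were drawn independently there, so this does not check the list test where members vary together. For cell numbers, a 16-fold fall of neutrophils was called in 36 of 50 simulations, and another class was called in 2 of 50.

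Alternatives fixed before the data were examined were DESeq2 1.42.0 as the test, DESeq2 size factors, no low-count filter, all cells summed, other cell filters, doublets kept, another resolution, clustering centred per library, thinning, a replicate block, the compared groups alone, and each library left out. Alternatives chosen after seeing the data were a minimum of 2500 UMIs in every library, macrophages with the cluster led by Chil3 and Arg1, macrophages without a low-UMI cluster, cells with Xist or with Y-linked RNA alone, lists within macrophage subtypes, shares outside the mixed clusters, clustering without the 512 genes called in any comparison, and other classes without genes higher in macrophages. The tests of chromosome 17 genes in fibroblasts, of endothelial genes against their whole macrophage level and of a swap of labels by called genes replaced earlier tests after those values and the levels were seen. The swap was tested in 3 forms, by the level of Gm10260, by the level of Srsf3 and by called genes, and when the last was chosen its counts of 83 and 175 genes were known. The overlap of the 2 comparisons was set against 30 simulations of unchanged groups. A first version of that simulation held no shared control values and was replaced. Figures were drawn with matplotlib 3.10.9.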

Results

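The series measured RNA in single cells of atherosclerotic arteries. Fluorescent cells, marked by Cre under the lysozyme M locus, were sorted from the aortic root, aorta and carotid arteries of Apoe-deficient mice on a high-cholesterol diet, with or without floxed Srsf3. Srsf3 encodes a splicing factor of the SR family, and the series concerns its effect on expression and transcript ends in lesional macrophages. WT mice were sampled after 12 weeks of diet (2 libraries) and after 30 weeks (2 libraries), and KO mice after 12 weeks (1 library). The files held 98748261 and 109599241 UMIs for WT 12-week replicates 1 and 2, 159976196 and 129742619 UMIs for WT 30-week replicates 1 and 2, and 105481312 UMIs for the library labelled KO. After filtering, 7578 and 8792 cells were kept at WT 12 weeks, 16816 and 11956 at WT 30 weeks, and 7726 in the library labelled KO. Median UMIs per kept cell were 9208.5 and 8834.5, 4635.5 and 5330.0, and 10492.5 in the same order.

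The libraries differed in ways that the groups do not explain. Cells with Xist RNA and no Y-linked RNA made up 70.2% of WT 12-week replicate 1 and 0.0% of WT 12-week replicate 2, 64.6% and 27.1% of the WT 30-week replicates, and 68.7% of the library labelled KO. Cells with Y-linked RNA alone made up 8.01%, 57.5%, 6.42%, 23.9% and 13.1%. Across genes in macrophages the replicates of a group correlated at r = 0.981 at WT 12 weeks and 0.983 at WT 30 weeks. Their counts differed by more than sampling noise (chi-square per degree of freedom 184 over 13643 genes and 236 over 13720 genes), so neither pair is a single library deposited under both names.

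Macrophages were the most frequent class in every WT library, and the vessel wall classes were also present in the sort. Macrophages made up 60.8% and 50.8% of cells at WT 12 weeks, 53.8% and 67.5% at WT 30 weeks, and 17.01% (exact 95% interval 16.2 to 17.9) of the library labelled KO. An unnamed cluster led by Chil3 and Arg1 made up 10.9%, 9.62%, 2.34%, 3.20% and 36.2% (35.2 to 37.3) in the same order of libraries. Mixed clusters of low UMI count, kept out of every class by a rule set after the data were seen, made up 1.66%, 9.39%, 35.8%, 8.75% and 0.466%. Within the macrophage class the libraries leaned on different clusters: a low-UMI foamy cluster (cluster 11) held 37.2% of macrophages in WT 30-week replicate 1 and between 2.28% and 8.26% in the other libraries, while the library labelled KO drew mainly on clusters 4, 1, 8 and 3. Summed macrophage UMIs were 58109688 and 48626468, 86165831 and 51039363, and 14912994.

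**Figure D1:**
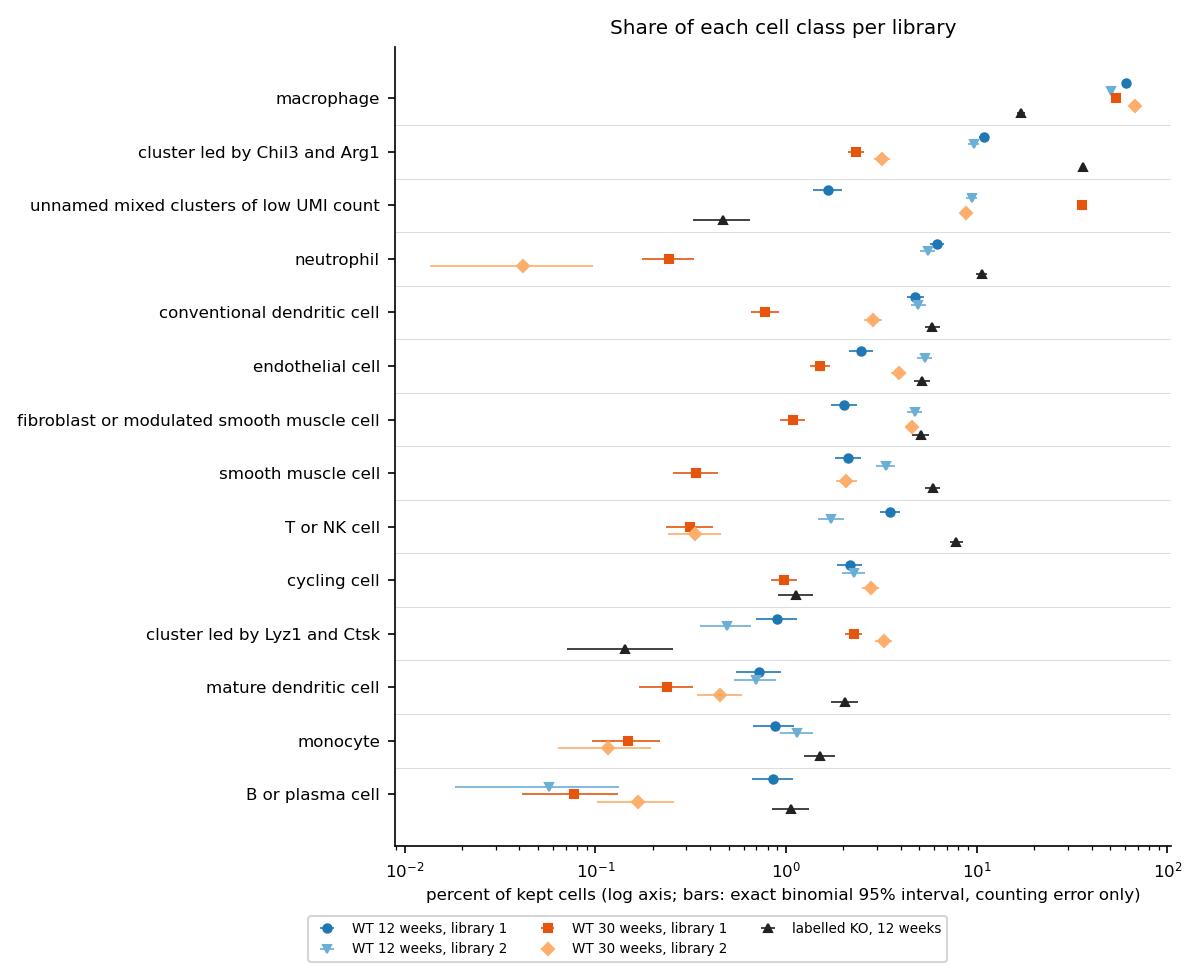
Share of each cell class among kept cells (percent, log axis) in each of the 5 libraries, with exact binomial 95% intervals that cover counting error only. Neutrophils were 6.19% and 5.53% of cells at WT 12 weeks and 0.244% and 0.0418% at WT 30 weeks.

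Srsf3, the targeted gene, was higher in the library labelled KO than in every WT library. In macrophages Srsf3 (ENSMUSG00000071172, mm10 chromosome 17, 29032628 to 29043373) was at 248 and 189 CPM at WT 12 weeks, 234 and 172 CPM at WT 30 weeks, and 469 CPM in the library labelled KO. The log2 fold change of the library labelled KO over WT at 12 weeks was 1.10 (SE 0.38) and did not pass (edgeR adjusted p = 0.576). At WT 30 weeks against 12 weeks it was -0.11 (SE 0.32, edgeR adjusted p = 0.997). Unscaled Srsf3 levels in the cluster led by Chil3 and Arg1 were 306, 267, 297 and 261 CPM in the WT libraries and 714 CPM in the library labelled KO, while in endothelial cells they were 294, 245, 258 and 226 CPM against 317 CPM. The assay counts 3' ends and the floxed exons are not given in the sources used here. A 3' tag outside the deleted part checks nothing, so these counts neither establish nor exclude a deletion.

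**Figure D2:**
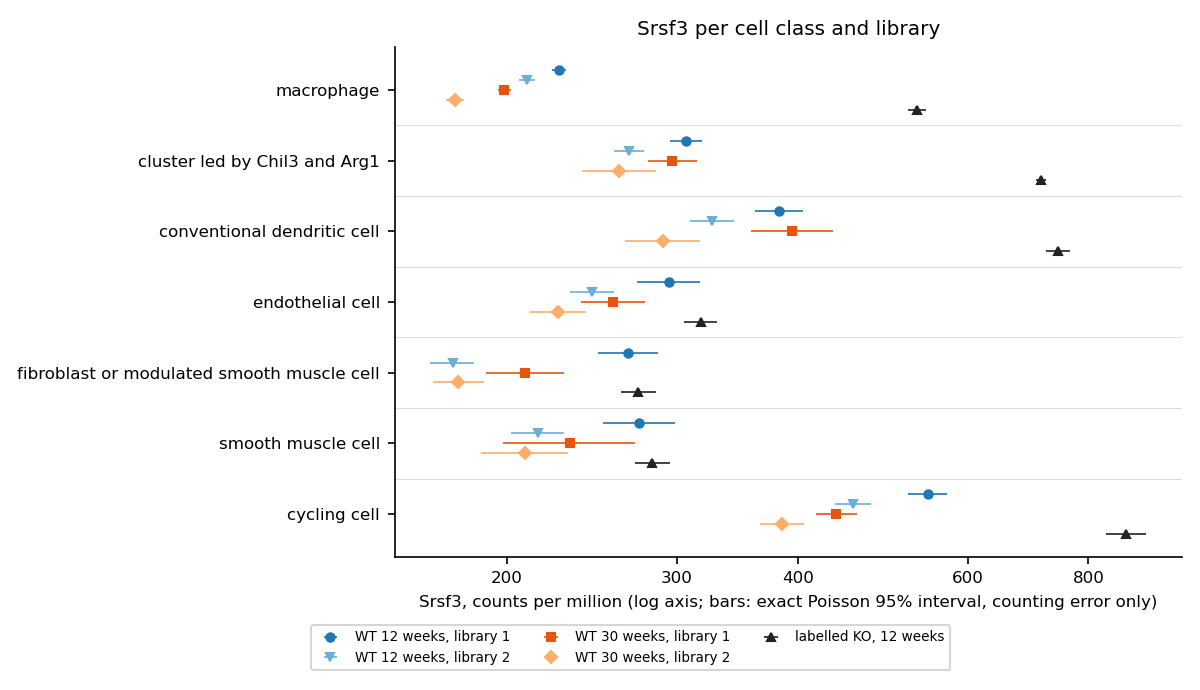
Srsf3 in CPM (log axis) per cell class and library, with exact Poisson 95% intervals for counting error only. In macrophages the unscaled levels were 226, 210, 199 and 177 CPM in the WT libraries and 531 CPM in the library labelled KO.

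The comparison of WT 30 weeks with WT 12 weeks asks how sorted lesional cells differ with longer diet. Kept cells had at least 2218 and 2502 UMIs in the WT 30-week replicates and at least 1000 at 12 weeks, so shares of classes of low UMI count are not measured alike. With these minima, neutrophils fell from 5.86% ± 0.468 (SD, n = 2) of cells to 0.143% ± 0.143 (SD, n = 2), a log2 change of -5.33 (SE 1.08). Monocytes fell from 1.00% ± 0.188 to 0.133% ± 0.0223 (log2 change -2.90, SE 0.81), and T or NK cells fell from 2.61% ± 1.25 to 0.325% ± 0.0137 (log2 change -3.00, SE 0.83). The edgeR adjusted p was 0.0148 for neutrophils, 0.0258 for monocytes and 0.0258 for T or NK cells, and the other 11 of 14 classes did not pass. Macrophages were at 55.8% ± 7.11 and 60.7% ± 9.68 (log2 change 0.12, SE 0.73, edgeR adjusted p = 0.872). With cells clustered without the 512 called genes, the same 3 classes passed (log2 change -4.11, SE 0.82, for neutrophils, -2.83, SE 0.51, for monocytes and -3.01, SE 0.62, for T or NK cells; edgeR adjusted p = 0.0470 for each). A minimum of 2000 UMIs and 1000 genes in every library left 0 classes past the threshold. Neutrophils then numbered 122 of 7016 and 200 of 7339 cells at 12 weeks and 192 of 16733 and 36 of 11913 at 30 weeks, where before there were 469, 486, 41 and 5. Their log2 change shrank to -1.62 (SE 1.06, edgeR adjusted p = 0.231). Monocytes numbered 6, 3, 2 and 0 cells at that minimum (log2 change -3.02, SE 1.43, edgeR adjusted p = 0.189), so hardly any are left to compare, and T or NK cells were at -3.16 (SE 1.12, edgeR adjusted p = 0.0950). With at least 2500 UMIs in every library, neutrophils were at -2.85 (SE 0.92) and T or NK cells at -3.38 (SE 0.95; edgeR adjusted p = 0.0405 for both). The size of the neutrophil fall thus depends on the UMI minimum and the clustering made with it. Leaving out WT 12-week replicate 1 or WT 30-week replicate 2 left 0 classes, and leaving out WT 12-week replicate 2 or WT 30-week replicate 1 left 1.

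In macrophages the scavenger receptor Cd163 (ENSMUSG00000008845, mm10 chromosome 6, 124304656 to 124330527) fell at 30 weeks, from 20.7 and 29.4 CPM to 3.36 and 3.31 CPM (log2 fold change -2.91, SE 0.30, edgeR adjusted p = 0.0321). It was the single call among 13987 genes, and simulated libraries with nothing changed gave 0 to 4 calls. Cd163 did not pass with all kept cells, where the edgeR adjusted p was 0.0841 (Cd163, WT 30 weeks vs 12 weeks), nor in 6 other settings; over all alternatives the adjusted p ran from 3.7e-15 to 0.0841. Lyve1, a hyaluronan receptor of resident macrophages, was at 29.4 and 83.3 CPM and then 5.57 and 6.98 CPM (log2 fold change -3.17, SE 0.47), and Ccr2, the receptor for monocyte chemokines, at 40.9 and 52.8 CPM and then 11.0 and 12.8 CPM (-1.97, SE 0.29). The neuronal adhesion gene Nrcam had the smallest p among genes with a higher level (log2 fold change 2.29, SE 0.30; 3.36 and 5.02 CPM, then 19.5 and 21.5 CPM). Lyve1, Ccr2, Ms4a4c (-1.92) and Nrcam each had an edgeR adjusted p of 0.0647 and did not pass. The other genes the rule names, also not past the threshold, had log2 fold changes from 1.15 (Plxdc1) to 1.71 (Uchl1) on the higher side, with Angptl2 at 1.51, Cspg4 at 1.45, Ephx1 at 1.45, Phlda3 at 1.39, Pcp4l1 at 1.32, Stmn4 at 1.29 and Serpinb6b at 1.25. On the lower side they ran from -1.25 (Thbs1) to -2.11 (F13a1), with C4b at -1.77, Ifi209 at -1.69, Hpgd at -1.47 and Retnla at -1.40. Cd163, Lyve1, F13a1 and Retnla are among the 10 leading genes of the resident cluster. Its share of macrophages went from 6.99% and 8.85% to 1.47% and 1.47%. Ccr2 and Hpgd are among those of cluster 1, which went from 22.4% and 25.9% to 4.24% and 8.01%. Sums over the macrophage class do not separate a fall per cell from this shift in cell mix.

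The list of interferon response genes fell at 30 weeks: all 27 measured members had lower levels (mean log2 fold change -1.08), 22 of them adjusted over the list alone, with Oasl1 at -1.46 (SE 0.33), Rtp4 at -1.23 (SE 0.30) and Ifi204 at -1.19 (SE 0.29). Resident macrophage genes also fell (17 of 19 lower, mean -0.94; 10 lower and 1 higher adjusted over the list alone), while resident macrophages went from 6.99% and 8.85% of macrophages to 1.47% and 1.47%. So did inflammatory cytokines and chemokines (17 of 19 lower, mean -0.66; 4 lower adjusted over the list alone), with Cxcl10 at -1.31 (SE 0.30) and Ccl8 at -1.15 (SE 0.33). Antigen presentation genes fell (15 of 16 lower, mean -0.66; 6 lower adjusted over the list alone), with the class II genes H2-Eb1 at -1.20 (SE 0.32), H2-Ab1 at -1.11 (SE 0.32) and Cd74 at -1.09 (SE 0.32). The macrophage cluster led by these class II genes and Ccr2 (cluster 1) went from 22.4% and 25.9% of macrophages to 4.24% and 8.01%. The camera adjusted p was 2.7e-31 for the interferon list, 8.1e-20 for resident genes, 5.3e-11 for cytokines and 6.2e-11 for antigen presentation. With an estimated correlation none held: the adjusted p = 0.654, 0.442, 0.654 and 0.442 with an estimated correlation in the same order. Of these members Cd163 alone passed over all genes. Of the 2 cytokine genes named, Ccl8 is also the leading gene of the resident macrophage cluster. The other, Cxcl10, is also a marker used to name interferon-responsive macrophages. They thus do not show a fall of cytokines apart from the falls of the resident and interferon lists. Within subtypes the interferon list was lower in all 4 (27 of 27 lower in foamy macrophages, mean -0.69), with adjusted p = 0.292 to 0.838 with an estimated correlation, whereas resident genes did not pass within foamy macrophages (mean 0.17, camera adjusted p = 0.702) or within resident macrophages (mean -0.01, camera adjusted p = 0.968). Resident genes were lower within the general subtype (mean -0.34, camera adjusted p = 0.00655; adjusted p = 0.635 with an estimated correlation). Antigen presentation genes were lower within the general, interferon-responsive and foamy subtypes (mean -1.01, -0.86 and -0.26; adjusted p = 0.292, 0.486 and 0.556 with an estimated correlation) and did not pass within resident macrophages (mean 0.06, camera adjusted p = 0.727).

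Lists of metabolism, matrix and other cell types were also called at 30 weeks. Nuclear-encoded oxidative phosphorylation genes rose (61 of 68 higher, mean 0.19), as did mitochondrially encoded genes (11 of 13, mean 0.42), glycolysis genes (14 of 18, mean 0.26), extracellular matrix remodelling genes (17 of 22, mean 0.36; 1 higher and 1 lower adjusted over the list alone) and senescence genes (7 of 11, mean 0.31). In the matrix list Fn1, fibronectin, was at 1.00 (SE 0.30) and Plau, a plasminogen activator, at -1.19 (SE 0.28). This list shares Col1a1, Col1a2 and Col3a1 with the fibroblast markers. The mitochondrial gene mt-Nd3 was at 245 CPM in WT 30-week replicate 1 and 684 CPM in replicate 2, against 182 and 259 CPM at 12 weeks. Markers of other cell types rose too: smooth muscle (9 of 10, mean 0.55), fibroblast (8 of 10, mean 0.74) and erythroid markers (4 of 4, mean 3.06; 1 adjusted over the list alone). Immediate early and heat shock genes, which mark dissociation stress, fell (17 of 21 lower, mean -0.29; 1 lower adjusted over the list alone), with Hspa1b at -1.51 (SE 0.34), and so did neutrophil markers (9 of 11 lower, mean -0.32). The camera adjusted p was 0.00302 for oxidative phosphorylation, 0.00886 for mitochondrial genes, 0.0132 for glycolysis, 0.0102 for matrix, 0.0371 for senescence, 0.00148 for smooth muscle, 0.00288 for fibroblast, 0.000368 for erythroid, 0.00513 for immediate early and 0.0157 for neutrophil lists. None held with an estimated correlation, where the adjusted p = 0.823 for oxidative phosphorylation and 0.671 for each of the others with an estimated correlation.

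The other 26 lists did not pass at 30 weeks. Their camera adjusted p ran from 0.0552 for autophagy to 0.890 for sex-linked genes, with 0.151 for foam cell genes (14 of 20 higher, mean 0.17), 0.277 for lysosome genes, 0.666 for LXR targets, 0.277 for the SR protein family, 0.589 for other splicing factors and 0.478 for cleavage and polyadenylation factors. The complement list had a median of 0.04 and a mean of -0.25 and was tested as lower (camera adjusted p = 0.128), with C4b at -1.77. Genes called by DESeq2 numbered 111 (41 higher, 70 lower), and 803 genes had an unadjusted edgeR p under 0.05. The number of called genes was 169 without WT 12-week replicate 1, 79 without WT 12-week replicate 2, 111 without WT 30-week replicate 1 and 86 without WT 30-week replicate 2.

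The comparison of the library labelled KO with WT at 12 weeks asks which cells and genes differ where Srsf3 is floxed. It sets 1 library against 2, assumes that the lone library varies like the other groups, and takes any direction from a label that the Srsf3 counts, higher there without passing, cannot check. The cluster led by Chil3 and Arg1 was 36.2% of cells in the library labelled KO and 10.3% ± 0.931 (SD, n = 2) at WT (log2 change 1.82, SE 0.86), and macrophages were 17.01% and 55.8% ± 7.11 (log2 change -1.71, SE 0.97). Neither passed (edgeR adjusted p = 0.294 for both). By edgeR 0 of 14 classes passed and 0 had an unadjusted p under 0.05; the lowest p, 0.05005, was that of the mixed clusters. With cells clustered without the 512 called genes, 2612 of 7726 cells in the library labelled KO fell into the cluster led by Chil3 and Arg1, against 787 of 7578 and 719 of 8792 at WT (log2 change 1.86, SE 0.56, edgeR adjusted p = 0.223). Clustering centred per library moved the macrophages of the library labelled KO from 1314 to 390 of 7726 cells and its cluster led by Chil3 and Arg1 from 2800 to 3718 cells, so the split between these classes depends on the clustering. There 1 class passed, the cluster led by Lyz1 and Ctsk (log2 change -8.65, SE 2.47, edgeR adjusted p = 0.0218; 0 cells in the library labelled KO).

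In macrophages 33 of 13987 genes differed between the library labelled KO and WT at 12 weeks, 19 higher and 14 lower. Lyz2, the lysozyme gene whose locus carries Cre in this strain (ENSMUSG00000069516, mm10 chromosome 10, 117277331 to 117282321), rose from 16.7 and 10.8 CPM to 845 CPM (log2 fold change 5.94, SE 0.49, edgeR adjusted p = 0.00115). A minority of cells carries this: 146 of its 1314 macrophages (11.1%, exact 95% interval 9.46 to 12.9) had at least 20 UMIs of Lyz2 and held 93.5% of its Lyz2 UMIs in macrophages. Without them the unscaled level was 71.1 CPM instead of 957 CPM, where endothelial cells and fibroblasts of this library were at 39.2 and 50.9 CPM. The lectin genes Cd209f (4.01, SE 0.35), Cd209g (4.03, SE 0.49), Cd207 (3.03, SE 0.34) and Fcna (2.83, SE 0.34) rose, as did lymphotoxin beta, Ltb (3.90, SE 0.35), and the class I gene H2-Q6 (3.03, SE 0.34). Cd5l, a secreted macrophage scavenger protein (ENSMUSG00000015854, mm10 chromosome 3, 87357881 to 87371073), fell from 441 and 311 CPM to 8.23 CPM (log2 fold change -5.51, SE 0.55, edgeR adjusted p = 0.00242). The natural killer receptor genes Klra8 (-4.02, SE 0.43) and Klra9 (-3.65, SE 0.41), the protease Htra1 (-3.57, SE 0.44), Hmga1 (-2.77, SE 0.42) and the serotonin receptor Htr2b (-2.74, SE 0.43) also fell, with edgeR adjusted p from 0.00439 for Klra8 to 0.0404 for Htr2b. The Cd209, Klra and H2-Q genes belong to families with near-identical copies among which reads may be split, so their separate levels are uncertain. Lyz2 in cells with Y-linked RNA alone had a log2 fold change of -0.88, so its call rests on cells with Xist RNA. Genotypes at the Lyz2 locus, which carries Cre, were not measured. The Lyz2 difference can therefore not be assigned to a loss of Srsf3.

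Of the 33 called genes 11 lie on chromosome 17 (33.3%, exact 95% interval 17.96 to 51.8), the chromosome of Srsf3, against 716 of the 13987 tested genes (5.12%; Fisher exact p = 4.0e-07). They are Tcte3, Hmga1, Msh5, Ltb, H2-Q1, H2-Q6, A930015D03Rik, Gm11127, Gm8909, H2-M2 and Epb41l3, of which 9 start within 10 Mb of Srsf3, as do 360 of the 716 tested. Apart from Hmga1 these 9 start between 35028605 (Msh5) and 37480851 (H2-M2). The Fisher test takes genes as independent, which neighbours in a short stretch of a single library may not be. Its p-value may thus overstate the enrichment. H2-Q1 was at 0.0344 and 0.0823 CPM at WT 12 weeks and 11.7 CPM in the library labelled KO (unscaled), and Gm11127 at 0.0688 and 0.0823 CPM against 9.86 CPM. The ribosomal-like predicted gene Gm10260 had an unscaled level of 0.293, 1.11, 0.232 and 1.74 CPM in the WT libraries and 167 CPM in the library labelled KO (edgeR adjusted p = 0.0701 in macrophages).

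**Figure D3:**
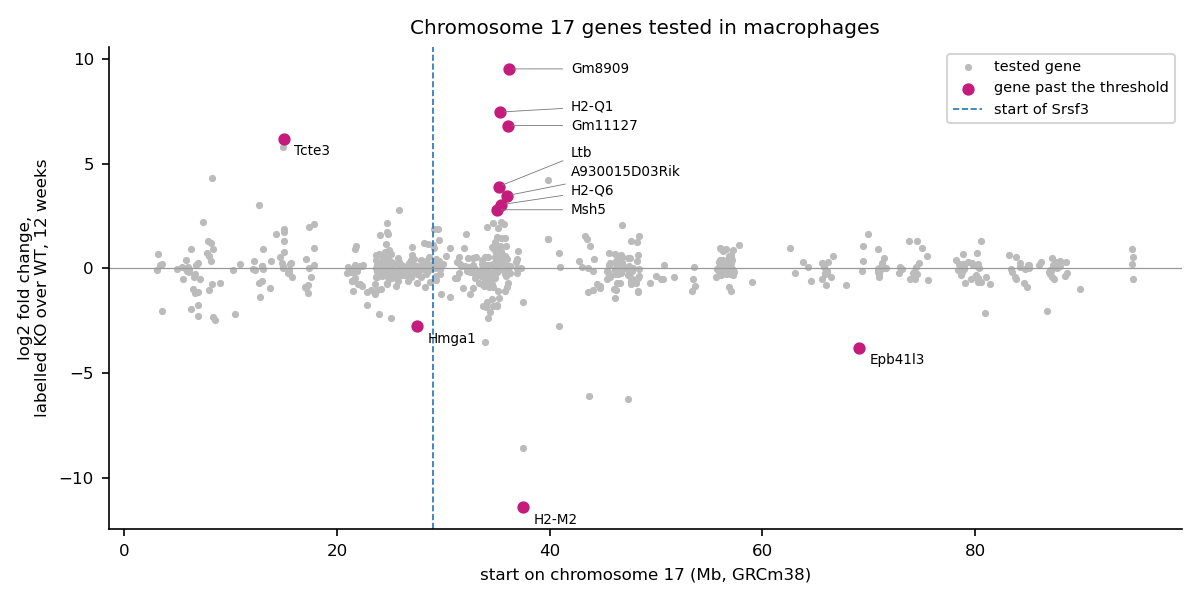
Log2 fold change in macrophages (library labelled KO over WT at 12 weeks) of 716 tested genes on chromosome 17 against their start in Mb. The 11 genes past the threshold are marked, and 9 of them start within 10 Mb of Srsf3, drawn as a dashed line, as do 360 of the 716 tested genes.

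Lipid-handling genes were lower in macrophages of the library labelled KO. Foam cell genes fell (0 of 20 higher, mean log2 fold change -1.33; 11 lower adjusted over the list alone), with the glycoprotein Gpnmb at -2.17 (SE 0.45), the proton pump subunit Atp6v0d2 at -2.11 (SE 0.46) and lipoprotein lipase, Lpl, at -1.59 (SE 0.41). Foamy macrophages were 22.2% of its macrophages, against 37.1% and 35.2% at WT 12 weeks. LXR targets fell (0 of 12 higher, mean -0.85; 3 lower adjusted over the list alone), with Scd1 at -1.65 (SE 0.36) and Apoe, disrupted in all these mice, at -1.49 (SE 0.36). Lysosome genes fell (36 of 38 lower, mean -0.57), with the cathepsin Ctsl at -2.41 (SE 0.66). Efferocytosis genes fell (14 of 20 lower, mean -0.75; 2 lower and 1 higher adjusted over the list alone, 1 lower over all genes), with Mfge8 at -2.41 (SE 0.57), and oxidative phosphorylation genes fell (55 of 68 lower, mean -0.17). The camera adjusted p was 1.1e-21 for foam cell genes, 7.7e-09 for LXR targets, 2.7e-09 for lysosome, 0.0105 for efferocytosis and 0.0372 for oxidative phosphorylation. None held with an estimated correlation: the adjusted p = 0.507, 0.507, 0.532, 0.507 and 0.935 with an estimated correlation in the same order. Within foamy macrophages the foam cell list was also lower (20 of 20, mean -0.84, camera adjusted p = 1.4e-08), as it was within the general subtype (20 of 20, mean -0.77, camera adjusted p = 8.2e-12), and within resident macrophages it did not pass (mean -0.22, camera adjusted p = 0.130). In the foamy and general subtypes the adjusted p = 0.652 and 0.584 with an estimated correlation.

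Other lists were higher in macrophages of the library labelled KO. Resident macrophage genes rose (15 of 19 higher, mean 0.82; 8 higher and 1 lower adjusted over the list alone), with Mgl2 at 1.53 (SE 0.36) and F13a1 at 1.59 (SE 0.42), and interferon response genes rose (26 of 27, mean 0.66; 1 higher adjusted over the list alone), with Isg15 at 1.46 (SE 0.33). Inflammatory cytokines and chemokines (18 of 19, mean 0.59), NF-kB feedback genes (15 of 19, mean 0.31), p53 targets (13 of 15, mean 0.32) and senescence genes (8 of 11, mean 0.81; 3 higher adjusted over the list alone) rose, with Ccl8 at 1.18 (SE 0.39), Nlrp3 at 0.95 (SE 0.33) and the cell cycle inhibitor Cdkn2a at 1.81 (SE 0.35). Markers of smooth muscle (10 of 10, mean 1.29; 4 higher adjusted over the list alone) and fibroblasts (7 of 10, mean 0.58) rose as well. The camera adjusted p was 1.0e-10 for resident genes, 4.5e-09 for interferon, 0.000109 for cytokines, 0.0188 for NF-kB feedback, 0.0310 for p53 targets, 8.3e-05 for senescence, 4.5e-09 for smooth muscle and 0.0255 for fibroblast markers. None held with an estimated correlation, where the adjusted p = 0.590 for fibroblast markers and 0.507 for each of the others with an estimated correlation. Smooth muscle markers were called higher within all 4 subtypes, NF-kB feedback genes in all but the foamy one, p53 targets in the general and foamy subtypes, senescence genes in the general and resident subtypes, and fibroblast markers in none. Cytokines were called higher in resident macrophages alone (mean 0.49, camera adjusted p = 0.00762) and not in the general (mean 0.05, camera adjusted p = 0.451), foamy (mean -0.32, 0.113) or interferon-responsive subtype (mean 0.03, 0.953). None of these subtype calls held, with adjusted p = 0.456 to 0.698 with an estimated correlation. The resident and interferon lists were not called higher within any subtype: resident genes were lower within foamy macrophages (mean -1.13, camera adjusted p = 1.6e-06), and interferon genes were lower within resident macrophages (mean -0.47, camera adjusted p = 2.1e-05). Neither held, with adjusted p = 0.463 and 0.603 with an estimated correlation. Resident macrophages were 19.2% of the macrophages in the library labelled KO and 6.99% and 8.85% at WT 12 weeks. Smooth muscle cells were 5.89% of all its cells against a mean of 2.73% at WT 12 weeks, and fibroblasts 5.07% against 3.37%. Neither share passed. RNA of these cells counted in macrophages was not tested.

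The other 27 lists did not pass in the library labelled KO. Their camera adjusted p ran from 0.0653 for scavenger receptors to 0.932 for antigen presentation, with 0.316 for the SR protein family, 0.635 for cleavage and polyadenylation factors, 0.834 for other splicing factors and 0.336 for nonsense-mediated decay. The antigen presentation list had a mean of 0.02 and a median of -0.15 and was tested as lower. With DESeq2 size factors all 13 lists called here and all 14 called at 30 weeks kept their direction and call, while with all kept cells 7 of the 13 and 9 of the 14 did (2 turned in each, 1 of them called the other way here). With 1 WT library left out 11 to 13 of the 13 lists kept their call. At 30 weeks 8 of 14 did without WT 12-week replicate 1, 10 of 14 without WT 12-week replicate 2, 11 of 13 without WT 30-week replicate 1 and 7 of 14 without WT 30-week replicate 2. By DESeq2 116 genes were called (50 higher, 66 lower), and 846 genes had an unadjusted edgeR p under 0.05. The number of called genes was 83 without WT 12-week replicate 1, 175 without WT 12-week replicate 2, 154 without WT 30-week replicate 1 and 154 without WT 30-week replicate 2, and all 33 genes remained in each of these fits. Clustering centred per library called 250 genes, 199 higher and 51 lower, 29 of the 33 among them. Fits with 1 library left out called more genes in all, so keeping the 33 there is a weak check. With all kept cells 2 of the 33 stayed, with doublets kept 20 and at 2000 UMIs and 1000 genes 22. The common cell filter kept 24, 2500 UMIs 21 and cells with Y-linked RNA 13. DESeq2 size factors and no low-count filter kept 33, DESeq2 32 and Leiden resolution 0.5 31.

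**Figure D4:**
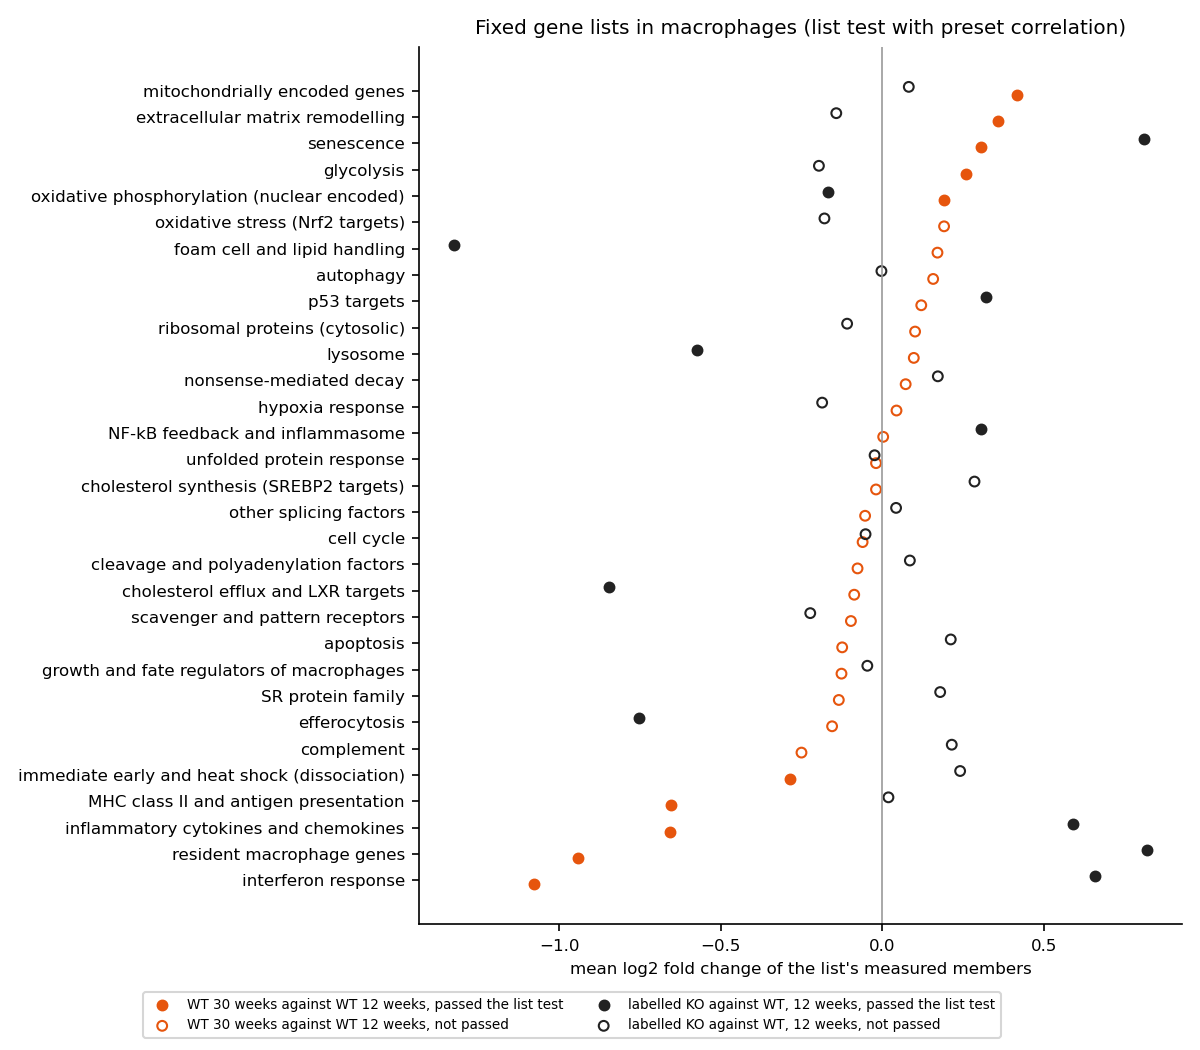
Mean log2 fold change of each fixed gene list in macrophages for WT 30 weeks over 12 weeks and for the library labelled KO over WT at 12 weeks; filled points passed the list test with a preset correlation. The interferon list lies at -1.08 and 0.66 and the foam cell list at 0.17 and -1.33, and none of the points passed with an estimated correlation.

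In other classes at WT 30 weeks, 436 calls (genes in other cell classes, WT 30 weeks vs 12 weeks) were made over 10 classes and macrophage subtypes, most of them in endothelial cells (178 higher, 47 lower), interferon-responsive macrophages (77) and fibroblasts (42 higher, 26 lower). In endothelial cells the matrix protease Mmp3 rose (log2 fold change 5.91, SE 0.50, edgeR adjusted p = 0.000335), as did Sprr2a3 (4.32) and the macrophage gene Adgre1 (3.05, SE 0.33), and the neutrophil genes S100a9 (-3.77, SE 0.35) and S100a8 (-3.45) fell. The macrophage gene C1qa was at 184 and 230 CPM in endothelial cells at WT 12 weeks and 1345 and 949 CPM at WT 30 weeks. In fibroblasts Mmp13 rose (2.42, SE 0.33), and Pi16 (-2.43, SE 0.33) and the transcription factor Tcf21 (-3.75, SE 0.50) fell. The other genes of smallest p there are the macrophage genes Fcrls (2.22) and Ms4a7 (1.90), and 37 of the 42 genes higher in fibroblasts are at a higher level in macrophages. In smooth muscle cells Hand2 (-2.56), Fbln1 (-2.71), S100a8 (-4.40), Pln (-2.65) and 2210407C18Rik (-1.76) fell, and in cycling cells Ifi205 (-2.99), Cxcl10 (-2.18), Gm42031 (-2.29), Ccr2 (-2.03) and Hspa1b (-2.13). The bone protease cathepsin K, Ctsk, rose in resident macrophages (4.71, SE 0.54), interferon-responsive macrophages (7.31, SE 0.57) and conventional dendritic cells (3.88, SE 0.54). In dendritic cells it is 1 of 3 genes called higher, Fcrls (1.91) among them, and all 3 are at a higher level in macrophages; Gm42031 (-2.32) fell there. Resident macrophages also had Npy (3.11), Gpnmb (2.54) and Mmp12 (2.36) higher and Cyr61 (-3.41) lower. Interferon-responsive macrophages had Folr2 (2.93), Mfge8 (3.04) and Npy (2.83) higher and Ccr2 (-3.57) lower, and the general subtype had Nrcam (2.51) and Cacna1a (1.98) higher and Ccr2 (-2.49), Ms4a4c (-2.50) and Ifi209 (-2.10) lower. The foamy subtype and the cluster led by Chil3 and Arg1 had 0 calls by edgeR, with 692 and 229 genes at an unadjusted p under 0.05. These counts depend on the setting: with 1 WT library left out they were 62 to 95 and 1 to 20, and with no low-count filter 159 and 17. With genes at a higher level in macrophages left out of the 3 vessel wall classes alone the total was 233, and with them left out of every class it was 194. With doublets kept, endothelial calls numbered 31 (20 higher, 11 lower). Calls in interferon-responsive macrophages numbered 25, 11 and 28 without WT 12-week replicate 1, WT 12-week replicate 2 and WT 30-week replicate 1. The total was 897 and 798 without WT 12-week replicates 1 and 2, and 760 and 786 without WT 30-week replicates 1 and 2.

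**Figure D5:**
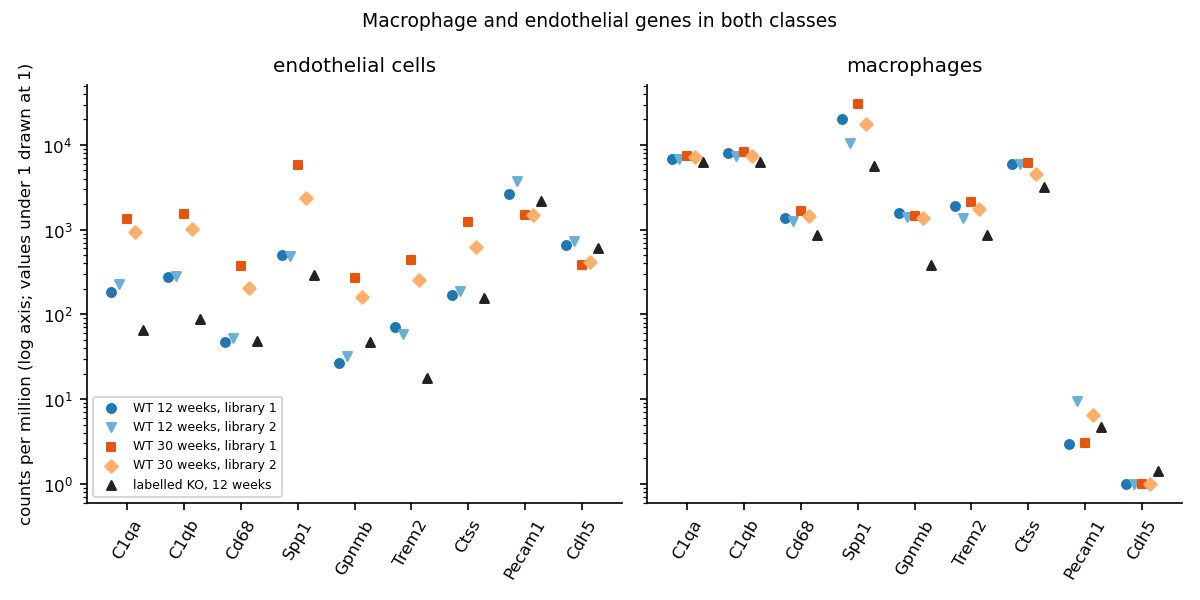
CPM (log axis, values under 1 drawn at 1) of macrophage and endothelial genes in endothelial cells and in macrophages of each library. C1qa in endothelial cells was at 184 and 230 CPM at WT 12 weeks and at 1345 and 949 CPM at WT 30 weeks, against 6773 to 7452 CPM in WT macrophages.

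In the library labelled KO, 311 calls (genes in other cell classes, KO vs WT at 12 weeks) were made over the same 10 classes and subtypes. Lyz2 and the predicted genes Gm10260, Gm11361 and Gm12166 were called higher in all 10, H2-Q1 in 8, and Cd5l was called lower in 7. Unscaled Lyz2 in endothelial cells of the library labelled KO was 39.2 CPM against 957 CPM in its macrophages, and abundant macrophage genes stood in its fibroblasts at a median of 4.22% of their macrophage level. Beyond these, the matrix protease Mmp3 (4.91, SE 0.52) and Cxcl10 (2.88, SE 0.39) rose in endothelial cells, proenkephalin, Penk (3.53, SE 0.36), and Cmah (4.25) rose in fibroblasts, Pgf (2.54) rose in conventional dendritic cells, Ltb (4.43) rose in cycling cells, H2-Q6 (3.47) rose in the cluster led by Chil3 and Arg1, and the cation transporter Slc22a3 (4.34, SE 0.46) rose in smooth muscle cells, where the macrophage genes C1qa (-2.98, SE 0.50) and Trem2 (-2.97, SE 0.50) fell. Of the 28 genes called lower in smooth muscle cells, 19 are at a higher level in macrophages, which were 17.01% of this library and 55.8% of cells at WT 12 weeks. Less macrophage RNA in that class was not tested. In macrophage subtypes Cxcl13 fell in resident macrophages (-5.37, SE 0.58), Cxcl9 rose in interferon-responsive macrophages (4.14, SE 0.50), and Retnla fell in the general subtype (-6.11, SE 0.56), where Ltb rose (4.37). H2-Q6 rose (4.72) and Cd5l fell (-4.86) in foamy macrophages. The histone gene Hist1h2ap was at 93.9 and 116 CPM in interferon-responsive macrophages at WT 12 weeks and at 0 CPM in the library labelled KO. The predicted genes may share reads with near-identical copies elsewhere, so their separate levels are uncertain. The total was 639 and 654 without WT 12-week replicates 1 and 2, and 893 and 864 without WT 30-week replicates 1 and 2.

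Fold changes of the 2 comparisons were related less than in simulations of unchanged groups. Both use the WT 12-week libraries, which alone gives a positive relation: across 13987 genes r was 0.0518, below each of 30 simulations of unchanged groups (mean 0.256, 0.229 to 0.286). The covariance was 0.0262 against a simulated 0.115 (difference -0.0893). Deviations of same-numbered WT replicates correlated at 0.526, and what this does to the simulated value was not tested. A covariance below the simulated one thus does not show that the changes ran against each other. Signs were the same in 50.4% of genes and in 62.4% in the simulations. Without WT 12-week replicate 1 or 2, r was 0.261 and 0.318 (covariance difference -0.0595 and -0.0449), still below the simulations. With no low-count filter r was 0.268, also below its simulations, but the covariance difference turned positive, 0.0432. No gene was called in both (0 both higher and 0 both lower; independent lists give 0 and 0.00100), with Cd163 the single call of one comparison. Without WT 12-week replicate 2, 13 genes were called higher and 3 lower in both, and 3 in opposite directions; without WT 12-week replicate 1 these counts were 1, 6 and 2.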

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

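The tests in this part were chosen only after the result was seen, and so were the 7 classes compared with endothelial cells.

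Srsf3 in the library labelled KO differed more from WT in myeloid and cycling cells than in endothelial cells. Against the change in endothelial cells, the log2 change of Srsf3 was larger by 0.905 (SE 0.17) in macrophages, 1.01 (SE 0.19) in the cluster led by Chil3 and Arg1, 0.869 (SE 0.23) in conventional dendritic cells, 2.20 (SE 0.74) in neutrophils and 0.570 (SE 0.19) in cycling cells. It was 0.02 (SE 0.19) in fibroblasts and -0.04 (SE 0.21) in smooth muscle cells. The edgeR adjusted p over the 7 classes was 0.00103, 0.000613, 0.00103, 0.00514 and 0.0121 for the first 5 and 0.921 for the last 2. Adjusted over all genes it was 0.0710, 0.0126, 0.0400, 0.532 and 0.341, so the macrophage difference passes only in the first form. These fits have 2 residual degrees of freedom and 1 library labelled KO, whose spread was not measured. Neutrophils numbered 41 and 5 cells in the WT 30-week libraries, under the minimum of 50 used elsewhere, so their value is the least certain.

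A strain variant acting in every class is argued against, because the macrophage change exceeds the endothelial change by 0.905 (SE 0.17). More counted 3' ends of Srsf3 after Cre acted in myeloid cells might account for the pattern: the lowest of 4 myeloid classes exceeds endothelial cells by 0.869, but Cre activity was not measured, so the data cannot tell. A swap of labels within the series is argued against: it would make the library labelled KO a replicate of its partner's replicate, yet these differ in 83 to 379 macrophage genes by edgeR, against 24 and 18 between the labelled replicates. With WT 12-week replicate 1 as the partner, genes at an unadjusted edgeR p under 0.05 were nearly as many between the labelled replicates. For that partner the argument thus rests on genes past the adjusted threshold alone. Srsf3 alone leaves a swap open, since its scaled level lies past the 95% prediction interval of the other 3 WT libraries for 2 of 4 partners and its unscaled level for each. A wrong label on this library alone stays open. Of its 33 called genes 9 start within 10 Mb of the floxed gene, as do 360 of the 716 tested genes on chromosome 17. Apart from Hmga1 these 9 start between 35028605 (Msh5) and 37480851 (H2-M2), with Srsf3 at 29032628. Genotypes were not measured, so whether these differences came with the floxed allele is unknown, and they do not decide the label.

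Outside that test, B or plasma cells went the other way, at 304 CPM (exact 95% interval 254 to 360) in the library labelled KO and 445 CPM (382 to 514) in WT 12-week replicate 1, while 20 cells of WT 30-week replicate 2 were at 229 CPM. T or NK cells were at 813 CPM in the library labelled KO and at 300.2 to 446 CPM in WT, but the class holds different cells: 267 of its 603 cells in the library labelled KO had Dntt or Rag1, and cluster 18 held 335 of its cells and 1 to 24 cells of each WT library.

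In the library labelled KO, 421 of 5659 myeloid cells (7.44%, exact 95% interval 6.77 to 8.15) held at least 20 UMIs of Lyz2, against 0 in each WT library, and 95.7% of these 421 cells had Xist RNA.

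T or NK cells with Dntt or Rag1, genes of antigen receptor recombination, made up 3.46% (3.06 to 3.89) of cells in the library labelled KO and 0.251%, 0.0341%, 0.0238% and 0.0251% of the WT libraries. Of macrophages, which should lack these genes, 0.152% had such a UMI in the library labelled KO and 0.0224% to 0.0434% in WT. The shares above are of all cells, so they cannot be set against this background. Of T or NK cells alone, 19 of 265, 3 of 152, 4 of 53 and 3 of 40 had such a UMI in the WT libraries, and 267 of 603 in the library labelled KO. In each library that lies above the macrophage background, but the 3 smallest WT counts are 3 or 4 cells. Median UMIs in the library labelled KO were 3506 in T or NK cells and 10159 in macrophages.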

How the results depend on the processing

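Alternatives on cells by Xist or Y-linked RNA, on subtypes, on the low-UMI cluster, on 2500 UMIs, on the Chil3 and Arg1 cluster and on genes above in macrophages were chosen only after the result was seen. Of the results the text leads with, 45 planned and 13 added alternatives moved the value, 2 turned its sign and 79 and 25 left it the same. Of the others, 20 planned and 1 added turned the sign, 99 and 12 were stronger, 46 and 15 weaker, and 696 and 189 the same. The cause was not tested.

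For macrophage genes at 30 weeks (1 call) there were 155 calls with no low-count filter, 111 with DESeq2, 15 after thinning to the smallest library, 10 with the Chil3 and Arg1 cluster added, 68 in cells with Xist RNA and 5 in cells with Y-linked RNA. There were 0 calls with all kept cells (1069 at unadjusted p under 0.05), doublets kept (799), 2000 UMIs and 1000 genes (771), centring per library (827), the common cell filter alone in WT 30-week replicate 2 (755), 2500 UMIs (776) and without the low-UMI macrophage cluster (822). Leaving out 1 library gave 1 to 169, the highest without WT 12-week replicate 1. For the library labelled KO (33 calls) there were 178 with no low-count filter, 4 with all kept cells, 116 with DESeq2, 159 with only the groups compared, 250 centred per library, 160 with Xist RNA and 17 with Y-linked RNA. Leaving out 1 library gave 83 to 175.

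With an estimated correlation 0 lists were called in either comparison. At the preset correlation, in the library labelled KO 7 were called in foamy and 7 in interferon-responsive macrophages, and at 30 weeks 9 in resident macrophages. Srsf3 at 30 weeks ran from -0.34 to 0.10 with 1 library left out. In the library labelled KO, Lyz2 was -0.88 in cells with Y-linked RNA and Htra1 0.12 with all kept cells. In other classes (genes in other cell classes, WT 30 weeks vs 12 weeks), calls were 1367 with no low-count filter, 233 with genes above in macrophages left out of the 3 vessel wall classes alone, 194 with them left out of every class and 407 to 897 with 1 library left out; in the library labelled KO they were 904 with no low-count filter, 197 with genes above in macrophages left out of every class and 639 to 893.

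At 30 weeks (3 classes) 5 shares passed with doublets kept, 0 at 2000 UMIs, 0 at 500 UMIs, 0 with TMM on cell numbers and 0 to 3 with 1 library left out. Cycling cells turned to 0.067 at 500 UMIs and 0.48 with TMM, endothelial cells to 0.22 and fibroblasts to 0.27 with TMM. With 1 library left out B cells ran from -2.81 to 1.08, endothelial cells from -1.37 to 0.13, fibroblasts from -1.64 to 0.48, macrophages from -0.051 to 0.28 and cycling cells from -1.17 to 0.33. In the library labelled KO 1 share passed when centred per library. Monocytes turned to -0.55 at 2000 UMIs, -0.51 with the common cell filter and -0.24 with TMM, where dendritic cells were -0.55, endothelial cells -0.42 and fibroblasts -0.24. Endothelial cells ran from -0.036 to 1.07 with 1 library left out.

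With the replicate number as a block, calls at 30 weeks were 1143 macrophage genes, 4492 in other classes (genes in other cell classes, WT 30 weeks vs 12 weeks) and 1 share. The labels do not state a pairing, and with 2 pairs the correlation of deviations, 0.526, does not show one.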

Other observations

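The tests of chromosome 17 and of endothelial cells in this part were chosen only after the result was seen, as were the lists within macrophage subtypes.

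Foam cell genes were at a higher level in the resident macrophage cluster at 30 weeks. Of 20 measured members 19 were higher (mean log2 fold change 1.23, camera adjusted p = 1.6e-35), a call lost with adjusted p = 0.838 with an estimated correlation. Gpnmb rose by 2.54 (SE 0.40, edgeR adjusted p = 0.0132) and the elastase Mmp12 by 2.36 (SE 0.39, edgeR adjusted p = 0.0158). The same list was higher in interferon-responsive macrophages (18 of 20, mean 0.72, camera adjusted p = 8.9e-12) and in the general subtype (18 of 20, mean 0.50, camera adjusted p = 2.7e-06), also lost with adjusted p = 0.486 and 0.635 with an estimated correlation, and did not pass in foamy macrophages (mean -0.06, camera adjusted p = 0.489). Of the 10 genes called higher in resident macrophages, 9 are at a higher level in macrophages as a whole, and RNA or cells of other macrophages in this cluster were not tested.

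In foamy macrophages of the library labelled KO, efferocytosis genes were lower in all 19 measured members (mean -1.70, camera adjusted p = 2.3e-10), a call lost with adjusted p = 0.463 with an estimated correlation. Antigen presentation genes were lower in its resident macrophages (11 of 15, mean -0.95, camera adjusted p = 1.2e-11), also lost with adjusted p = 0.603 with an estimated correlation.

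Genes called in the library labelled KO cluster on chromosome 17. An effect of gene lists that any comparison shows is argued against, because 3.03% of the 33 genes of smallest p at 30 weeks lie there. A stretch of another strain's chromosome carried with the floxed allele may account for it, but the data cannot tell: of 7 genes tested in fibroblasts 2 (28.6%, exact 95% interval 3.67 to 71.0), H2-Q1 and Hmga1, were called there in the same direction, and genotypes were not measured. Loss of Srsf3 acting in macrophages cannot be told apart either: the size of the change in fibroblasts, sign left aside, was 69.0% of that in macrophages in the median (bootstrap 95% interval 20.7 to 102), with 6 of 7 of the same sign and Epb41l3 at 0.79 against -3.79. Some changes are not confined to macrophages: H2-Q1 was called in 8 of 10 classes and subtypes, at 8.48 in endothelial cells and 7.63 in fibroblasts. In endothelial cells A930015D03Rik (3.51) also changed as much as in macrophages, while Ltb, H2-Q6 and Hmga1 changed less. Gm11127 was at 8.41 and H2-M2 at -4.03 there. H2-Q1, Gm11127 and H2-M2 had almost no UMIs in a group, so the size of their log2 fold changes depends on the prior count. Sizes of these 3 are not compared between classes, and the median of 69.0% includes H2-Q1 and Gm11127. In fibroblasts all 8 raised genes were over 3 times the 4.22% for macrophage RNA, at 17.9% (Msh5) to 115% (A930015D03Rik) of their macrophage level. H2-Q1 was at 40.9%, and Gm8909 and Tcte3 had only 4 and 6 UMIs there.

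Genes higher in endothelial cells at 30 weeks are mostly macrophage genes, 158 of 178. Macrophage RNA or cells counted in the endothelial cluster could account for those: 49 of the 50 most abundant macrophage genes (98%) gained there, by a median 14.3% of their macrophage level (quartiles 12.8 to 15.4), which fits. The other 20 genes were picked as not higher in macrophages. This nearly fixed in advance that their gain would exceed their whole macrophage level, as it did in 19 (95%), so that count is no test. Single genes did gain more than macrophage RNA at its whole level could bring. Examples are Mmp3 (2.48 to 153 CPM, 8.47 CPM in macrophages) and the protease inhibitor Timp1 (147 to 514 CPM, 30.7 CPM in macrophages). RNA of fibroblasts was not tested. A difference in depth is argued against, because 174 genes were called higher after thinning to the smallest total, while with doublets kept 20 were.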
